A study of Mus musculus with 63 samples.

How the data were processed

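Single mouse embryos at the 2-cell stage were profiled by Smart-Seq2, a full-length RNA-seq method for very small samples, with paired reads of 150 bases, per the labels. Zygotes were taken 17 h after the hCG injection that triggers ovulation and were frozen at 46 h. The 63 libraries form 5 groups. Cdk9in embryos (13 libraries) were cultured with BAY1251152, an inhibitor of the kinase Cdk9, and Noinject embryos (10) without it. The other groups underwent Trim-Away, in which an antibody and the ubiquitin ligase Trim21 remove a protein. The antibody was against SPT5 (Spt5KD, 18 libraries), against NELF-E (NelfEKD, 8) or a control IgG (IgG, 14). Library codes fall into a MUC and an L series, and replicate names carry a set letter from A to F whose meaning is not given in the sources used here. The groups Noinject and NelfEKD have libraries of the MUC series only. Nothing in the labels says which embryos shared a mating or a day, so p-values measure the spread between these embryos.

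The deposited values are read counts per gene in the layout of STAR's gene count output, 1 table per library, with 55487 genes, 92 ERCC spike-ins, 1 sequence of the injected mCherry-Trim21 construct and summary lines for reads not assigned to a gene. Of all reads in a used library, 9.50% to 61.6% were unmapped, 4.05% to 16.8% mapped to several places and 4.38% to 18.8% lay in no annotated gene, and these stayed out of library sizes. STAR 2.7.6a, RSEM 1.3.3, bedtools 2.29.0 and the genome build GRCm38 are named per the submitters' processing notes, which give no roles. Each table has 3 count columns, and the first, which ignores strand, was used. Reads from a gene and from an overlapping gene on the other strand can then not be told apart. Reads that map to several places are outside the gene counts, so genes with near-identical copies, which include many of the 2-cell stage list, are counted only where reads are unique. Gene symbols, positions and lengths come from GENCODE M21 on GRCm38. It named 55141 of the 55487 genes, and the other 346 keep their identifier.

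Gene counts per library ranged from 326610 to 5258591 (median 2338476) in the 61 libraries used. The Spt5KD libraries B_1 and E_3, with 119 and 6 gene counts, were left out of every test, which departs from the design of all 63 libraries. Counts are of reads without molecular identifiers, so counting intervals and floors cover counting error only. No pair of libraries within a group agreed within sampling noise (lowest chi-square per degree of freedom 6.7), and each was counted as 1 replicate. Pairs from different groups were not compared this way, so alike libraries across groups would not have been found.

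Genes were tested with edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3, after edgeR's low-count filter and TMM scaling, in 1 fit of all 61 libraries with group and library series as terms. In all, 14807 genes were tested in 6 comparisons, with Benjamini-Hochberg adjusted p under 0.05 as threshold. Errors of log2 fold changes are standard errors (SE). Of 21 gene lists written from general knowledge, the 19 with at least 5 tested members were tested with camera (limma 3.58.1) on voom values, at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether a list moves on balance in one direction. The lists cover genes switched on at the 2-cell stage, maternal or oocyte transcripts, ribosomal proteins, ribosome biogenesis, replication-dependent histones, immediate early genes, heat shock proteins, p53 targets, interferon response, proteasome, nuclear and mitochondrial genes of the respiratory chain, splicing, translation factors, pluripotency and lineage transcription factors, polymerase II pausing and elongation, DNA replication and mitosis. Markers of cumulus and granulosa cells, blood and sperm were added as other cell types the samples could hold. Library shares were compared by permutation tests of the difference of means, 2-sided, exact where a group has under 10 libraries and with 100000 resamples otherwise. Genes detected were also counted after thinning each library to 300000 gene counts.

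The genes named were chosen by a fixed rule. In each comparison it takes the 6 largest rises and 6 largest falls among genes past the threshold with an average log2 CPM of at least 3 and the same sign in each set letter of the treated group with at least 2 libraries. It adds the 2 members of each list with the smallest p, and Trim21, Supt5, Nelfe and Cdk9. Some genes the rule takes are not reported here. This rule, the lists, the design and the first set of alternatives were fixed before the data were examined. Where a gene had 0 counts in a group, the fold was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts, the ratio of summed CPM (counts scaled to library size) is given with its exact binomial interval at a level of 95%.

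Alternatives were RLE scaling, library totals, scaling to the maternal list or to spike-ins, no or a stricter low-count filter (5 CPM in 8 libraries), a prior that is not robust, no series term, the set letter as a block, each series alone, each set letter left out, only the groups compared, DESeq2 1.42.0, limma voom with quality weights, and leaving out libraries with under 70% of the median number of detected genes or under a set part of the median depth. After the data were seen, fits were added without the library labelled Cdk9in D_3, without Trim-Away libraries under 500 construct CPM, with the near-empty libraries, in the MUC series alone with either set of libraries left out, scaled to spike-ins without 3 libraries over 10-fold from the median of gene counts per spike-in count, without IgG A_2, and without NelfEKD B_1. Library shares were compared without the library labelled Cdk9in D_3 as well.

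The gene test was tested on simulated data with 200 changed genes among 14807. Of genes changed by 8-fold it called 49.3% for Cdk9in against Noinject, 68.7% for Spt5KD against IgG, 43.3% for NelfEKD against IgG and 46.3% for IgG against Noinject. At 4-fold the shares were 19.4%, 26.9%, 16.4% and 23.9%, and at 2-fold 3.0%, 7.6%, 3.0% and 4.5%. Between 1 and 4 unchanged genes were called. The simulated changes were balanced between up and down, so uneven directions, where scaling matters, were not simulated. For Cdk9in against Noinject 7998 real genes were called, which makes the adjusted threshold less strict than in the simulation. The simulated shares do not apply to it. Other splits of the libraries were drawn within library series, 40 per result with the real one included, and only among the groups compared. For the difference of the Spt5KD change between series, series labels were exchanged within each group instead.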

Results

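The 61 libraries came from single 2-cell embryos, 13 Cdk9in, 10 Noinject, 16 Spt5KD, 8 NelfEKD and 14 IgG. Median gene counts were 2410092, 2288579, 2238561, 2486357 and 2240132 in that order. Cdk9, SPT5 and NELF are factors of RNA polymerase II pausing and elongation, and the comparisons ask how transcripts of the embryo depend on each.

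RNA of the injected Trim21 construct was found in the Trim-Away groups, at 2538 ± 1505 CPM in IgG (SD, n = 14), 2578 ± 479 in NelfEKD (n = 8) and 3018 ± 2145 in Spt5KD (n = 16). In Noinject it was 18.4 ± 10.6 CPM (n = 10). All 14 IgG libraries lay above every Noinject library (permutation test, adjusted p = 0.00016 over 16 tests, from the smallest p these permutations can give). Among the Cdk9in libraries 1, labelled D_3, held 5403 CPM of the construct, and is called the library labelled Cdk9in D_3 throughout. Cdk9in means and fold changes include it unless stated. Trim-Away removes protein, so the mRNA of a target checks no depletion. Supt5 mRNA was 51.9 ± 35.8 CPM in Spt5KD and 116 ± 62.8 in IgG, with a log2 fold change of -1.04 ± 0.49 (SE, edgeR adjusted p = 0.173). Nelfe mRNA was 81.4 ± 55.1 CPM in NelfEKD and 82.8 ± 52.1 in IgG (log2 fold change 0.33 ± 0.82, adjusted p = 1). The NelfEKD libraries are of the MUC series only, where Nelfe in IgG was 56.7 ± 38.7 CPM (n = 9). The endogenous Trim21 gene had 0 CPM in all 61 libraries. Reads that match both this gene and the construct would count for neither, so the 0 does not show that the gene was silent.

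**Figure D1:**
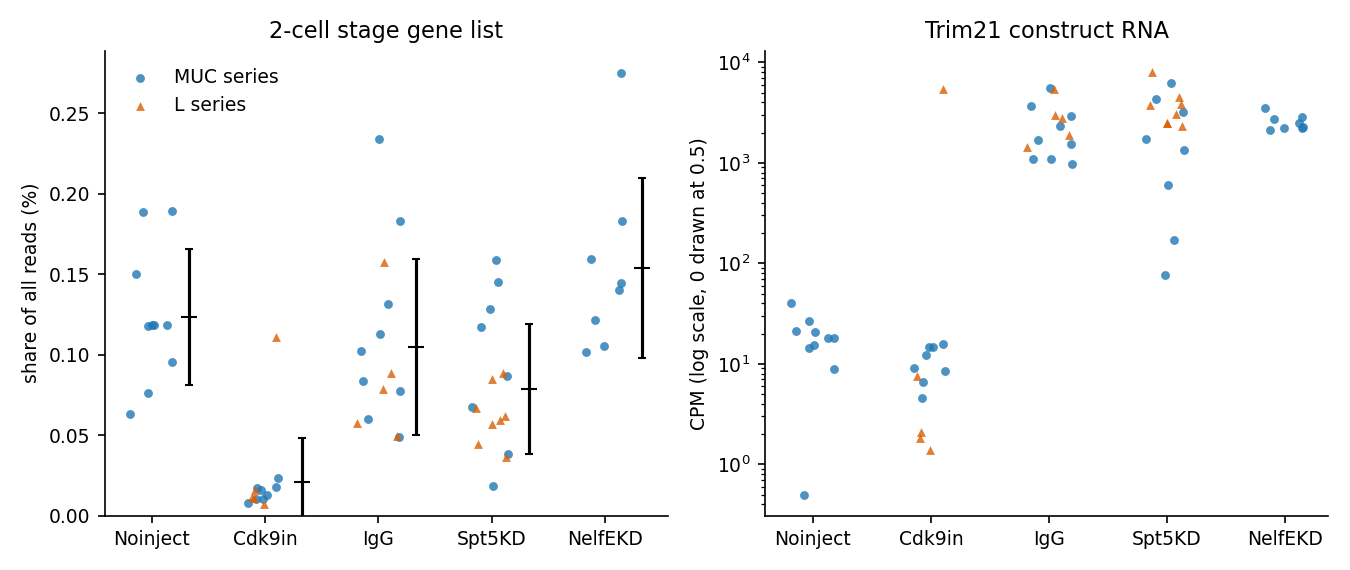
Each point is 1 embryo library of the group on the x axis, with circles for the MUC and triangles for the L series. The left panel gives reads of the 2-cell stage list as percent of all reads, with mean and SD bars (Cdk9in 0.0210%, Noinject 0.124%), and the right panel the construct RNA in CPM on a log axis, where 1 Cdk9in library stands at 5403 CPM.

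Culture with the Cdk9 inhibitor went with low levels of transcripts that embryos make at the 2-cell stage and high levels of transcripts stored in the egg. Of 40 tested genes of the 2-cell stage list 37 fell and 1 rose, among them the PRAME family gene Pramef6 (log2 fold change -7.47 ± 1.03 SE) and the deubiquitinase gene Usp17la (-7.29 ± 1.03), both of multigene families with shared sequence. Of 51 maternal or oocyte transcripts 36 rose and 4 fell (7 and 10 when scaled to that list itself), with Spin1 (2.065 ± 0.251), a meiotic spindle-associated factor, and Wee2 (2.14 ± 0.27), an oocyte kinase. Of 89 ribosomal protein genes 86 fell, such as Rplp1 (-3.76 ± 0.51) and Rpl34 (-3.36 ± 0.51), and of 59 ribosome biogenesis genes 57 fell, such as the nucleolar Ncl (-2.60 ± 0.38) and Npm1 (-2.32 ± 0.35). Adjusted over the list alone, 37, 86 and 58 members of the 2-cell, ribosomal protein and biogenesis lists fell and 38 of the maternal list rose. The share of all reads from the 2-cell list was 0.0210% ± 0.0274 (SD, n = 13) against 0.124% ± 0.0422 (n = 10), below every Noinject library in all but the library labelled Cdk9in D_3 (0.111%), 12 of 13 (permutation test, adjusted p = 0.00032, from the smallest p these permutations can give). Without that library it was 0.0135% ± 0.00472 (n = 12, adjusted p = 0.00032 by the same test).

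Some genes of other basic functions fell as well. Like the lists above, theirs did not pass camera with an estimated correlation (adjusted p = 0.312 to 0.757). In splicing 44 of 61 genes fell, with Snrpd1 (-2.48 ± 0.43) and Sf3b5 (-3.27 ± 0.57), and in translation 32 of 41, with Eef2 (-1.99 ± 0.31) and Eif4g1 (-2.01 ± 0.34). Of the proteasome 25 of 34 fell and 2 rose, with Psma3 at -3.68 ± 0.68. For the respiratory chain 42 of 75 nuclear genes fell, with Cox4i1 at -4.06 ± 0.78, while of 13 mitochondrial genes only mt-Nd1 (0.70 ± 0.30) passed the test, at -0.93 with maternal scaling. Of 34 pausing and elongation genes 22 fell and 2 rose. Supt5 (-3.69 ± 0.65), Nelfe (-3.66 ± 0.90) and Cdk9 itself (-4.01 ± 0.76) fell (-4.24, -4.54 and -5.41 without the library labelled Cdk9in D_3), and Mllt3 (1.96 ± 0.26) rose. In DNA replication 23 of 43 fell and 4 rose, with Cdt1 (-2.78 ± 0.42), a licensing factor, and Pold3 (1.92 ± 0.27), and in mitosis 15 of 25 fell and 4 rose, with Incenp (-2.997 ± 0.553) and Plk1 (-2.03 ± 0.46). Adjusted over the list alone these counts were the same, except for 45 splicing genes lower and 0 mitochondrial genes higher.

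The camera test passed for 11 of 19 lists, with the maternal list up (adjusted p = 1.32e-09) and 10 down, among them ribosomal proteins (2.81e-28), ribosome biogenesis (1.05e-18) and the 2-cell list (1.51e-11). With an estimated correlation none of the 19 passed (adjusted p = 0.182 for these 4 lists). Immediate early genes (13 of 22 fell, with Ier2 at -5.59 ± 0.87), heat shock proteins (11 of 19, with Hsp90ab1 at -3.03 ± 0.48) and pluripotency or lineage factors (13 of 20, with Prdm14 at -6.27 ± 1.26) missed the list threshold at an adjusted p of 0.0505 each. Lists of p53 targets (9 fell and 3 rose of 19), interferon response (8 fell and 2 rose of 14), histones (0 of 8 called), mitochondrial genes and blood markers (2 of 5 fell) did not pass. Of 22 cumulus and granulosa markers 4 passed the low-count filter and 2 fell, and of 8 sperm markers 0 passed it, too few for a list test.

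In single genes, 7998 of 14807 differed, 2684 higher and 5314 lower in Cdk9in. The largest rises were Cyp2b23 (7.20 ± 1.20), a cytochrome P450 gene, the non-coding Gm10280 (4.90 ± 1.13), Dock2 (4.87 ± 1.37), Ube2d1 (4.81 ± 1.27), the processed pseudogene Gm6018 (4.725 ± 1.185), whose reads may be shared with its parent gene, and Cd200 (4.69 ± 1.17). Cyp2b23 lies on chromosome 7 from 26665227 to 26686437 and stood at 31.6 ± 17.9 CPM (SD, n = 13) against 0.129 ± 0.306 (n = 10). Among the largest falls Sigirr was at least 361-fold lower, Mgat3 at least 196-fold and the Y-linked Uty and Usp9y at least 390-fold and 347-fold, with 0 counts in all 13 libraries. Uty and Usp9y were counted in 8 of 10 Noinject embryos. The sex of the embryos was not known here, so the folds of these Y-linked genes do not measure the change with the inhibitor. The 13 libraries include the one labelled Cdk9in D_3, so genes well counted in it could not fall as far. For Gal3st2 the 2 counts in 1 Cdk9in library against 866 gave a 746-fold lower ratio (counting interval 206 to 6170).

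The direction of calls depended on the scaling. Against 33.6% of calls higher with TMM, RLE scaling gave 1654 higher and 6098 lower, spike-ins 655 and 5095 (1767 and 5142 without 3 libraries far from the rest in spike-ins), and the maternal list 320 and 8537. The median over all genes was -0.57 with TMM, -1.05 with RLE, -0.97 with spike-ins (-0.70 without those 3) and -2.10 with the maternal list. Relative to that median the maternal list stood 1.84 to 1.90 higher and the 2-cell list between -4.75 and -3.11 under these scalings and library totals. A change of scaling shifts most genes alike, so such a difference does not test whether the maternal rise holds under other scalings. Without the set-B libraries 4761 genes were called, and without the library labelled Cdk9in D_3 8767 (2892 higher and 5875 lower). In libraries thinned to equal depth 9548 ± 1396 genes were detected in Cdk9in and 12350 ± 888 in Noinject (adjusted p = 0.00016, permutation test, from the smallest p they can give). The ribosomal RNA gene with most counts made up 5.57% ± 5.30 of gene counts in Cdk9in and 14.45% ± 6.605 in Noinject (permutation test, adjusted p = 0.0132), and 8.64% against 14.45% in the MUC series (exact, adjusted p = 0.255).

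**Figure D2:**
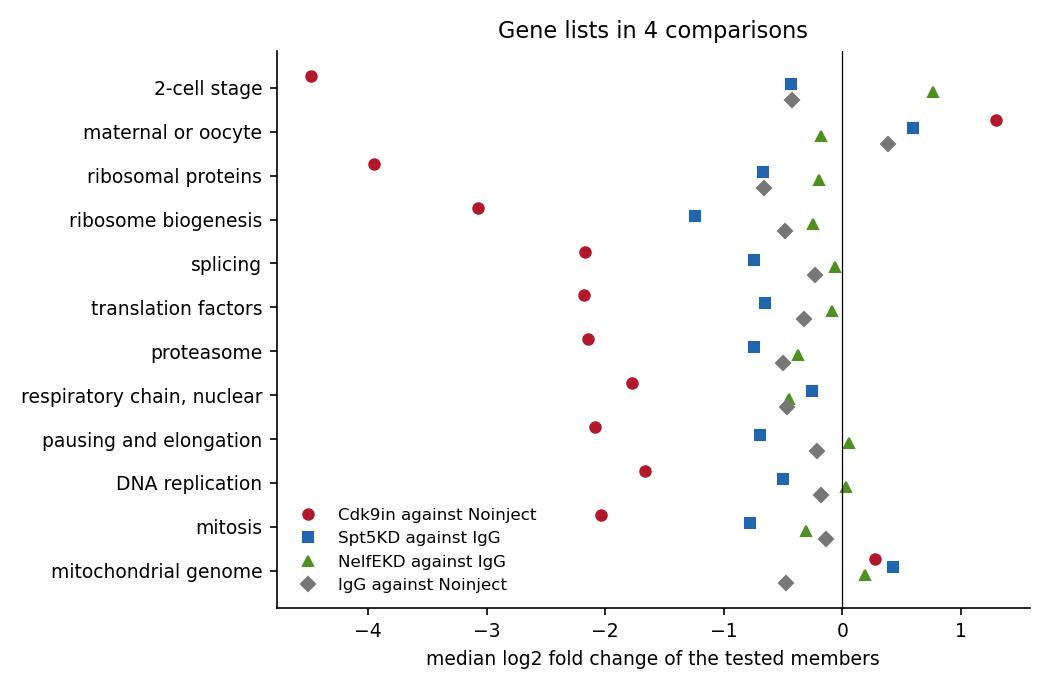
Each symbol is the median log2 fold change (x axis) of the tested members of the gene list on the y axis, with 1 symbol per comparison. The 2-cell list stands at -4.48 (-4.41 with the 1 member at 0 counts set at its bound) for Cdk9in against Noinject, -0.44 for Spt5KD against IgG and 0.77 for NelfEKD against IgG with TMM scaling, and these values depend on the scaling.

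In Spt5KD embryos, some maternal transcripts stood higher than in IgG embryos and a few genes of ribosome assembly and translation lower. Of 51 maternal or oocyte transcripts 15 rose and 1 fell (0 and 0 with spike-ins, 2 and 8 when scaled to that list), with Btg4 (1.67 ± 0.29), an adaptor of maternal mRNA decay, and Spin1 (1.26 ± 0.21). Of 59 ribosome biogenesis genes 5 fell, with Lyar (-1.64 ± 0.36) and Ncl (-1.10 ± 0.31), and the list's median was -1.25. In translation 6 of 41 fell, with Eif3h (-1.63 ± 0.40) and Eif4h (-1.91 ± 0.51), in splicing 5 of 61, with Hnrnpf at -0.62 ± 0.18, and in the proteasome 2 of 34, with Psma2 at -1.06 ± 0.28. Adjusted over the list alone, 18 maternal transcripts rose and 7 biogenesis, 7 translation, 5 splicing and 2 proteasome genes fell. Of the 2-cell list 0 of 40 passed, with a median of -0.44.

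The largest rises were Bhlhe23, a transcription factor gene with 1212 counts in 11 of 16 libraries against 2 counts in 1 of 14 (ratio 551, counting interval 152 to 4550), Gstm1 (7.02 ± 1.34), a glutathione transferase gene, the stress-induced factor gene Atf3 (5.85 ± 1.18), Lhx6 (5.73 ± 1.19), Mycl (5.43 ± 1.25) and the odorant receptor gene Olfr1104 (4.94 ± 0.96). Atf3 stood at 29.0 ± 29.3 CPM (SD, n = 16) against 0.455 ± 1.05 (n = 14). Among the largest falls were Rpp38 (-2.91 ± 0.83), a subunit of ribonuclease P, C1s2 (-2.72 ± 0.90), Cxcl16 (-2.60 ± 0.77), Ppp1r16b (-2.54 ± 0.82) and Zscan26 (-2.36 ± 0.75). Grk6 (-4.10 ± 1.16) rested on 1 library, IgG A_2, without which it was -1.56 (adjusted p = 0.282), and the IgG level was 4.93 ± 5.69 CPM of library totals (n = 13). Among list members with a smaller change, Btg2 (2.10 ± 0.51), Pou5f1 (1.70 ± 0.43), Mllt3 (1.22 ± 0.22) and Pold3 (1.13 ± 0.22) rose, the last 2 at -0.38 and -0.45 with spike-in scaling.

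Camera passed for 13 of 19 lists, down for ribosome biogenesis (adjusted p = 1.47e-25), ribosomal proteins (4.16e-18, although 0 of 89 fell and 1, Rps27l, rose, at -0.11 with spike-ins) and splicing (1.39e-11), and up for the maternal list (0.000764). With an estimated correlation none passed (adjusted p = 0.255 for the first 3 and 0.317 for the maternal list). Blood markers passed as well (0.0246), with 1 of 5 members past the test, Lyz2 at 3.99 ± 1.15.

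In all 1076 genes differed, 911 higher and 165 lower. RLE scaling gave 404 higher and 242 lower, the fit of only the compared groups 528 and 587, and the maternal list 105 and 1279, while spike-ins called 44. Of the libraries 3 lay over 10-fold from the median of 32.1 gene counts per spike-in count, IgG A_2 (0.661), IgG E_1 (940.5) and Spt5KD D_4 (2.84). Without them spike-ins called 54 genes, 53 higher and 1 lower, with an all-gene median of 0.30, and Mllt3 stood at 1.29, Pold3 at 1.15 and Rps27l at 0.98. The all-gene median was 0.13 with TMM, -0.12 with RLE, -0.71 with the maternal list and -0.95 with spike-ins of all libraries. Relative to it the maternal list stood 0.34 to 0.47 higher and the biogenesis list between -1.38 and -0.84, differences that a change of scaling can hardly alter. Within series, the L libraries (8 against 5) gave 1887 genes and the MUC libraries (8 against 9) 0 by edgeR, with 734 at an unadjusted p under 0.05. Without the set-D or set-E libraries 24 and 107 were called, and without low-quality libraries 2753. Without the library labelled Cdk9in D_3 there were 2230, 1277 higher and 953 lower, so the balance of directions depended on this library too.

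**Figure D3:**
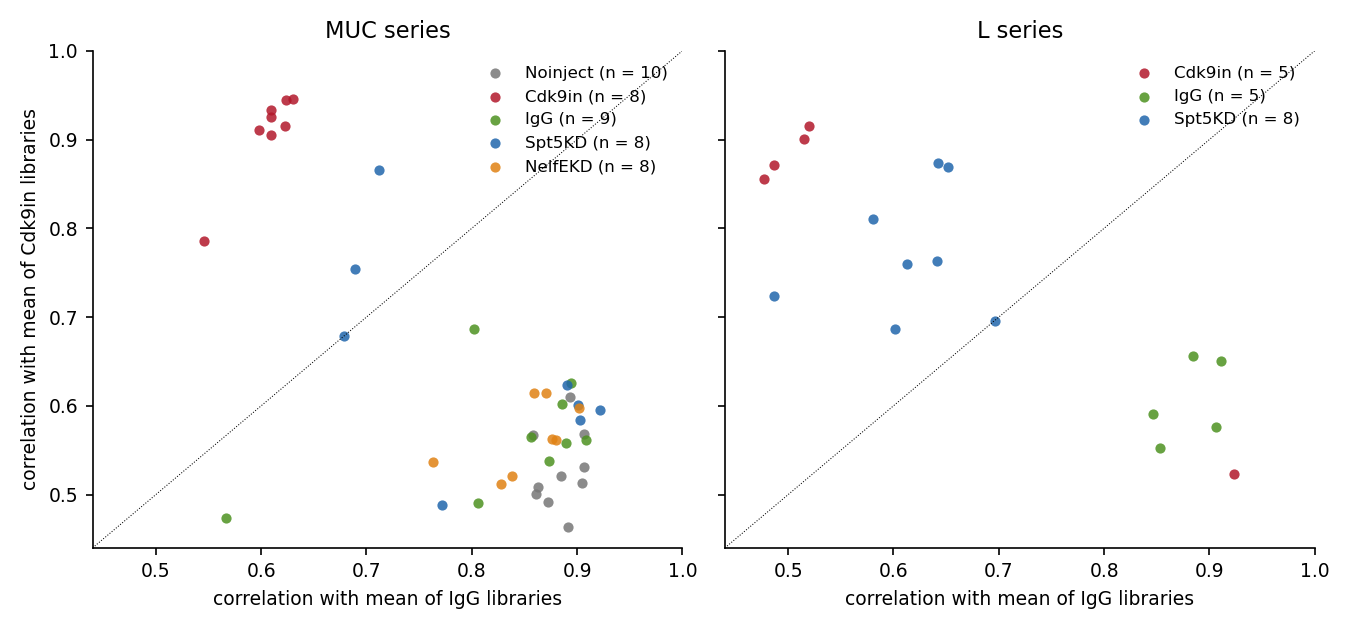
Each point is a library, placed by the correlation over genes of its log2 CPM with the mean of the IgG libraries (x axis) and of the Cdk9in libraries (y axis) of its own series, itself left out, with MUC on the left and L on the right. The library labelled Cdk9in D_3 lies at 0.923 and 0.523 in the right panel, and the dotted line marks equal correlation.

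In NelfEKD embryos few single genes differed from IgG. Psma2, a proteasome subunit gene, fell (-1.98 ± 0.38, 31.3 ± 13.4 CPM in 8 against 112 ± 31.8 in 14 libraries), as did Cops8 (-1.23 ± 0.24), of the COP9 signalosome, and Orc6 (-1.09 ± 0.22), of the origin recognition complex, with adjusted p of 0.0233, 0.0233 and 0.0245. No gene rose past the threshold in this fit. Among the alternatives 1 rose without NelfEKD B_1, 1 without set F, 3 without low-quality libraries, 5 by DESeq2, 10 by voom with quality weights and 298 with no low-count filter. In the other alternatives none rose. Of the 2-cell list 0 of 40 passed and 33 of 40 had positive values, with a median of 0.77 and Usp17la at 2.32 ± 0.83. The library NelfEKD B_1 stood apart in reads of this list (0.275% of all reads, next 0.183%), and without it 33 of 40 were positive, with a median of 0.48 and Usp17la at 2.19 ± 0.86. Nuclear respiratory chain genes had a median of -0.45, with 0 of 75 called.

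The 3 calls were among 886 genes at an unadjusted p under 0.05. DESeq2 called 32 and voom with quality weights 55, while spike-in or maternal scaling and the fit of only the compared groups called 0. Camera passed for 5 lists, with the 2-cell list up and the respiratory chain down (adjusted p = 5.21e-06 each, 0.000349 and 5.76e-06 without NelfEKD B_1), and none with an estimated correlation (0.968). The direct comparison of Spt5KD and NelfEKD called 473 genes, 370 of them higher in Spt5KD, and 0 in the MUC series or in the fit of only these groups, where edgeR had 947 at an unadjusted p under 0.05.

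IgG and Noinject embryos, compared for the effect of injection, had 0 called genes by edgeR, with 610 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by voom with quality weights. Ribosomal protein genes had a median of -0.66 (0 of 89 called) and maternal transcripts of 0.38 (0 of 51), and both passed camera (adjusted p = 3.43e-10 and 2.86e-06), with 0.674 at an estimated correlation.

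Fold changes of the inhibitor and of the SPT5 depletion, which share no control, were correlated across genes. Of the genes higher in Spt5KD 700 were also higher in Cdk9in (165.1 for independent lists), and 153 were lower in both (59.2). In opposite directions 43 and 0 were shared (326.9 and 29.9). Pearson's r was 0.538 over 14807 genes, which are not independent replicates, against 0.032 in simulated unchanged groups, and 0.309 in the MUC series. The changes themselves differed for 1973 genes, 1792 of them lower in Cdk9in relative to its control, for 5013 in the MUC series, 4669 without the library labelled Cdk9in D_3 and 713 with spike-ins (1737 without the 3 libraries far from the rest). For Spt5KD and NelfEKD, which share the IgG libraries, r was 0.263 against 0.390 (0.374 to 0.410) in simulated unchanged groups. The covariance was 0.322 against 0.292 (0.272 to 0.311), above every simulation. With the IgG libraries split in 2 parts r was 0.061 (-0.055 to 0.143) and the covariance 0.094 (-0.098 to 0.207), both ranges with 0 inside. Splits of the real libraries reached an r of 0.607, and 35 of 40 were as high as the real one. Real libraries thus spread more than the simulated ones, so no shared change can be read from the covariance.

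Shorter genes had lower fold changes in Cdk9in. With genes split into 4 equal groups by genomic span, from the shortest to the longest, the median log2 fold changes were -2.07, -1.12, -0.46 and 0.56, with Spearman's rho 0.290 across 14775 genes and 0.144 with exonic length in place of span. For Spt5KD rho was 0.106 (0.003 with exonic length, 0.053 in the MUC series), for NelfEKD 0.094 and for IgG against Noinject 0.120.

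Reads that map to several places made up 10.91% ± 2.697 of all reads in Cdk9in and 7.25% ± 1.70 in Noinject (permutation test, adjusted p = 0.00544, above all Noinject in 9 of 13). In Spt5KD they were 8.96% ± 2.51 against 6.92% ± 1.74 in IgG (adjusted p = 0.0493, above all IgG in 3 of 16). Within the L series this was 10.4% against 6.83%, above all IgG in 8 of 8 (exact permutation test, adjusted p = 0.00622), and within MUC 7.49% against 6.97% (exact, adjusted p = 0.688). Of 16 share comparisons 3 passed. No-feature and mitochondrial shares passed in none of the 16. Without low-quality libraries the mitochondrial share passed in Spt5KD (1.92% against 1.22% in IgG) and in IgG (1.22% against 1.90% in Noinject), at an adjusted p of 0.0348 each by permutation tests. These tests have no series term, and Noinject has MUC libraries only. In the MUC series, with low-quality libraries kept, the shares were 1.95% in Spt5KD, 1.46% in IgG and 1.90% in Noinject. Neither comparison passed there (exact permutation tests, adjusted p = 0.405 each). In the L series the no-feature share passed in Spt5KD (11.2% against 8.70% in IgG, exact permutation test, adjusted p = 0.0280). The Spt5KD difference in reads that map to several places lies at the threshold, with an adjusted p of 0.0451 to 0.0541 over 20 other draws of resamples, of which 12 passed. It did not pass without low-quality libraries (adjusted p = 0.053) or as a share of reads assigned to genes (0.556), by permutation tests.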

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

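The tests on the library labelled Cdk9in D_3, the test of the difference between library series, its splits, the comparison of construct level with profile and the fits within the MUC series without some libraries were chosen after the result was seen.

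The library labelled Cdk9in D_3 held 5403 CPM of the injected construct, a sequence outside the gene comparisons, where Noinject libraries held at most 39.99 CPM. Its profile correlated with the mean IgG profile of its library series at 0.923 and with the other Cdk9in libraries of that series at 0.523, a difference of 0.4, so a wrong label may account for it. A small carry-over is argued against, since even from the library richest in construct a share of 67.1% would be needed. It had 77.4 CPM of Cdk9, 83.9 of Supt5 and 107 of Nelfe, where the other Cdk9in libraries had at most 7.055, 21.01 and 20.75. With the correlations these values argue against an injected embryo that had the profile of the inhibitor. How the label came about stays open, and no biological explanation was tested. In several values the library lay close to IgG D_3, a library of the same series and replicate name. Construct RNA was 5403 and 5395 CPM, gene counts per spike-in count 18.98 and 19.05, and genes detected 15814 and 15923. Mitochondrial genes made up 3.45% and 2.77% of gene counts. Whether both hold RNA of 1 embryo was not tested, and they were counted as separate replicates. With the library labelled Cdk9in D_3 left out of the mean, the other 4 Cdk9in libraries of the L series correlated with Cdk9in at 0.868 to 0.931 and with IgG at 0.477 to 0.520.

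The change of Spt5KD against IgG differed between the library series for 77 of 10921 genes by the edgeR test of the difference (1881 at an unadjusted p under 0.05). In 40 splits with the series labels exchanged within each group, which keep the treatment effect, only the real one gave as many (1 of 40, highest other 0). The other splits had 72 to 402 genes at an unadjusted p under 0.05, below the 5% that chance gives. They may understate chance, so their counts do not exclude it. Of 915 called genes tested in both series 909 had the same direction, with a median size of 0.70 (log2) in MUC and 1.97 in L. These genes were called in the fit of both series together, which favours a shared direction and large sizes, so this count does not test agreement. Over all 12436 genes tested in both series, the fold changes of MUC and L correlated at r = 0.426. Little construct in some MUC libraries and low-quality MUC libraries are argued against as the whole cause, since the MUC series gave 0 and 1 genes without them. A part stays open, since genes at an unadjusted p under 0.05 went from 734 to 1046 and 1479, and the calls of Spt5KD against NelfEKD in that series from 0 to 34 and 315. Whether the amount of construct goes with a Cdk9in-like profile cannot be told apart from chance over 8 MUC libraries (rho -0.119, exact permutation p = 0.793, r -0.00254, exact p = 0.989, adjusted 0.882 and 0.989 over both series). Without the 2 libraries farthest in construct, A_2 and B_2, r was -0.926. Of those left, the set-C libraries (3247 to 6179 CPM) correlated best with the mean of IgG or Noinject. Those of sets A and B (603 to 1713 CPM) correlated best with Cdk9in or Spt5KD. This r thus cannot tell the amount of construct from the set letter. A difference in depletion between the series may remain, as nothing here measured protein.

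In 4 of 26 tests for a library far from the rest of its group a library stood apart, where chance gives about 1 in 20. Only NelfEKD and Noinject were tested this way, as the other groups hold more libraries than the test allows. Libraries of Cdk9in, IgG and Spt5KD that lie far from their group were not looked for here. The share of gene counts from 1 ribosomal RNA gene on chromosome 17 was 35.8% in NelfEKD C_1 (next highest 11.7%). No-feature reads made up 18.8% in NelfEKD A_2 (next 10.5%) and 14.5% in Noinject B_1 (next 11.2%). Reads of the 2-cell list made up 0.275% of all reads in NelfEKD B_1 (next 0.183%).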

How the results depend on the processing

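The fits without the library labelled Cdk9in D_3, without Trim-Away libraries low in construct, with the near-empty libraries, in the MUC series with libraries left out with spike-ins but without the 3 libraries far from the rest in spike-ins, without IgG A_2 and without NelfEKD B_1 were chosen after seeing the data. The cause was not tested for any change below, except that fewer libraries or genes enter some fits. Among the named genes' values under the alternatives, 1479 kept direction and side of the threshold, 27 lost the call, 4 gained it and 3 changed sign in Cdk9in against Noinject. In Spt5KD against IgG these were 1124, 328, 64 and 15, in NelfEKD against IgG 1160, 37, 12 and 0, and in IgG against Noinject 1174 and 0 others. Of library shares 62 values kept both, 3 lost and 3 gained the call. Counts of called genes within 1.5 times the reported one ran from 5750 to 10712 for Cdk9in against Noinject, 836 to 1446 for Spt5KD against IgG, 2 to 4 for NelfEKD against IgG, 331 to 666 for Spt5KD against NelfEKD and 1494 to 2798 for the difference of the Cdk9in and Spt5KD changes. Depth limits low genes, and libraries differ from 326610 to 5258591 gene counts.

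The number of called genes in Cdk9in against Noinject was 12942 with no low-count filter and 4761 to 8222 with a set left out. In Spt5KD against IgG it was 646 with RLE, 44 with spike-ins (54 without the 3 libraries), 4803 with no filter, 0 in MUC, 1887 in L, 2753 without low-quality libraries, 1646 by DESeq2, 6531 by voom with quality weights and 24 to 2208 with a set left out. It was 2230 without the library labelled Cdk9in D_3, 1932 without libraries low in construct, 0 and 1 in MUC without those or low-quality libraries, and 637 with the near-empty libraries. In NelfEKD against IgG it was 0 by edgeR with totals, the maternal list, spike-ins with or without the 3 libraries, only the groups compared or the near-empty libraries, 355 with no filter, 1 in MUC, 12 without low-quality libraries, 5 without IgG A_2, 32 by DESeq2, 55 by voom and 0 to 4 with a set left out. In IgG against Noinject it was 242 with no filter, 3 by DESeq2 and 0 to 0 with a set left out.

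In Spt5KD against NelfEKD it was 314 with RLE, 7 with spike-ins (57 without the 3 libraries), 2391 with no filter, 812 with no series term, 0 in MUC and with only the groups compared, 1643 without low-quality libraries, 3939 by voom, 1004 without libraries low in construct, 34 and 315 in MUC without those or low-quality libraries, 257 with the near-empty libraries and 0 to 1014 with a set left out. The difference of the Cdk9in and Spt5KD changes had 713 genes with spike-ins, 5324 with no filter, 5013 in MUC, 3120 by DESeq2, 5287 by voom, 4669 without the library labelled Cdk9in D_3, 4844 and 5122 in MUC without libraries low in construct or low-quality, and 773 to 4544 with a set left out.

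With an estimated correlation 0 lists passed in each of the 4 comparisons. By fry 17 passed in Cdk9in against Noinject, 13 in Spt5KD against IgG and 0 in NelfEKD against IgG and IgG against Noinject. By camera in the MUC series alone, 2 passed in NelfEKD against IgG. The correlation of the Cdk9in and Spt5KD changes was 0.728 for genes with an average log2 CPM of at least 3 and 0.309 in MUC. That of Spt5KD and NelfEKD was 0.431 in MUC, 0.183 without low-quality libraries, 0.358 without the library labelled Cdk9in D_3 and 0.061 with the IgG libraries split. For gene span, rho in Cdk9in was 0.309 for protein-coding genes, 0.144 with exonic length and 0.305 in MUC. In Spt5KD it was 0.158 for genes with a log2 CPM of at least 3, 0.003 with exonic length and 0.053 in MUC, and in NelfEKD 0.149 for genes with a log2 CPM of at least 3.

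With scaling to the maternal list, Trp53inp1 (-0.39), mt-Nd1 (-0.93) and mt-Nd2 (-1.14) changed sign in Cdk9in against Noinject, and Rps27l (-0.24), mt-Nd5 (-0.03), mt-Nd1 (-0.10), Polr2c (-0.30) and Mad2l1 (-0.23) in Spt5KD against IgG. With spike-ins, Rps27l (-0.11), Rrm2b (-0.38), Cmpk2 (-0.97), mt-Nd5 (-0.43), mt-Nd1 (-0.46), Mllt3 (-0.38), Polr2c (-0.47), Pold3 (-0.45), Cdc25b (-0.11) and Mad2l1 (-0.19) changed sign in Spt5KD against IgG. Without IgG A_2, IgG E_1 and Spt5KD D_4, over 10-fold from the median of gene counts per spike-in count, none of these genes changed sign.

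Mean profiles of sets with the same letter did not deviate together across the groups compared, and alikeness of libraries within a set was not tested. Construct RNA did go with the letter in 2 groups. It was 2958 to 5627 CPM in set C of IgG (973 to 2348 in sets A and B). In Spt5KD it was 3247 to 6179 (76.3 to 1713), but in NelfEKD 2238 to 2759 (2128 to 3557). Correlations of same-letter deviations ran from -0.032 to 0.011 for Cdk9in and Noinject, -0.372 to -0.016 for Spt5KD and IgG, -0.071 to 0.124 for NelfEKD and IgG and -0.156 to 0.012 for IgG and Noinject. With the letter as a block the counts were 8309, 836, 3, 0, 366 and, for the difference of changes, 3320, with 12, 16, 5 and 7 lists and correlations of 0.498 and 0.240.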

Other observations

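The counts of libraries by nearest group profile and the counts of splits in the direction of the span trend were chosen after the result was seen, and the tests by splits and by gene span before it.

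In Spt5KD against IgG, some inducible genes rose singly. By camera the p53 list (adjusted p = 0.894), the interferon list (0.544) and the immediate early list (0.0637) did not pass, while the mitosis list passed downward (0.000173, median -0.78), although not with an estimated correlation (0.255). Of the p53 targets 2 of 19 rose, Perp (log2 fold change 5.16 ± 1.15 SE), a membrane protein gene, and Rrm2b (1.09 ± 0.24), a ribonucleotide reductase subunit gene, whose value was -0.38 with spike-in scaling (1.29 without 3 libraries far from the rest in spike-ins). Of the interferon response list 2 of 14 rose, the RNA sensor gene Ddx58 (2.97 ± 0.74) and Cmpk2 (1.66 ± 0.54), the latter at -0.97 with spike-ins (1.71 without those 3). Of immediate early genes 3 of 22 rose and of the mitosis list 3 of 25, with Cdc25b, a phosphatase that activates Cdk1, at 1.99 ± 0.59 (-0.11 with spike-ins, 2.38 without those 3). Adjusted over the list alone, 4 p53 targets rose and 1 fell, and 2 interferon, 4 immediate early and 3 mitosis genes rose, with 4 of the last list lower.

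By the group profile a library correlated with best within its series, itself left out, 12 of 13 Cdk9in libraries were nearest to Cdk9in and 8 of 8 NelfEKD to NelfEKD. Those 12 correlated with Cdk9in at 0.786 to 0.946 and with IgG at 0.477 to 0.63. The NelfEKD libraries were nearly as close to IgG (0.763 to 0.902) as to NelfEKD (0.767 to 0.905), so their count shows little separation. Of the 8 L libraries of Spt5KD 7 were nearest to Spt5KD and 1 to Cdk9in. Of its 8 MUC libraries 3 were nearest to Noinject, 2 to Cdk9in and 1 each to Spt5KD, IgG and NelfEKD. The controls were not all nearest to their own group either. Of the 9 MUC libraries of IgG 0 were nearest to IgG, 7 to Noinject and 2 to Spt5KD, while 5 of 5 L libraries of IgG were nearest to IgG and 9 of 10 Noinject libraries to Noinject. The L series holds no Noinject or NelfEKD profile to be nearest to, so these counts cannot be compared between the series.

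Among 40 splits of the libraries within series, the real one included, only the real split called as many genes for Cdk9in against Noinject (6322, highest other 2), Spt5KD against IgG (1115, highest other 0) and the difference between both changes (1494, highest other 1), each 1 of 40, and gave as high a correlation of the Cdk9in and Spt5KD changes (0.538, highest other 0.354), also 1 of 40. For the counts of genes this argues against chance, at the smallest share that 40 splits can give. For the correlation the other splits exchange treated and control libraries and so remove both changes. They show that groups without an effect gave lower values, not that 2 real changes are alike. Cdk9in libraries of the L series have no Noinject library to be exchanged with, so they kept their label in splits of Cdk9in and Noinject. For NelfEKD against IgG (0 genes, highest other 1), IgG against Noinject (0, highest other 0) and Spt5KD against NelfEKD (0, highest other 33) the fits of the groups compared called no gene. Any split is as large as that, 40 of 40 in each, so these splits say nothing about chance. In those fits edgeR left 590, 1078 and 947 genes at an unadjusted p under 0.05. For lists passing camera, 7 of 40 splits gave as many in Cdk9in against Noinject (11, highest other 13), 2 in Spt5KD against IgG (12, highest other 12), 17 in NelfEKD against IgG (3, highest other 9) and 4 in IgG against Noinject (8, highest other 11), so chance is not excluded for the numbers of lists. The correlation of the Spt5KD and NelfEKD changes (0.264, highest other 0.607) was reached by 35 of 40.

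Fold changes in Cdk9in against Noinject were higher in longer genes, and this pattern was tested for causes. With expression level removed from both, the rank correlation of fold change and gene span was 0.274, and with exonic length removed 0.266, which argues against either as the whole cause. Splits of the libraries gave as large a correlation, of either sign, in 5 of 40 (real 0.267, highest other 0.285), and in the real direction in 3, so chance is not excluded. Nor is it for Spt5KD against IgG, with 5 of either sign (0.146, highest other 0.182) and 2 in the real direction (highest other 0.147). For NelfEKD against IgG it was 3 of either sign (0.130, highest other 0.168) and 2 in the real direction (0.152), so chance is not excluded there.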
